A study of Mus musculus with 2 samples.

How the data were processed

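Chromatin immunoprecipitation followed by sequencing (ChIP-seq) recovers the DNA fragments bound by a protein with an antibody and maps them to the genome by sequencing. The series holds 2 libraries from cerebral cortex of embryonic day 15 CD1 mice, an outbred stock. One library came from a precipitation with an antibody against Satb2, and the other was labelled as input with no ChIP antibody. Per the labels' protocols, the cortices were fixed in 1% formaldehyde and sonicated, and the ChIP-seq library was read from both ends, 100 nt each, on a Genome Analyzer II from Illumina. The labels name 1 library of each kind, so there was no replicate of either, and the numbers in the library names were not treated as replicate numbers.

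The data were a single deposited list of peaks in mm9 coordinates, the genome build named in the file header. Reads were aligned with Bowtie and peaks were called with MACS, a caller that scores windows of read enrichment against a local background, per the submitters' processing notes. Versions, settings and the way in which the input entered the call are not given in the sources used here. For each peak the authors deposited a chromosome, a start, an end, a name and a score, which is 10 times the −log10 of the caller's p-value. The smallest deposited score was 50, a p-value of 1e-05. Peak numbers in the names ran from 1 to 1341 with 0 missing, and the list held 0 duplicated and 0 overlapping intervals. Every peak lay on chromosomes 1 to 19 or X. Whether the start counts from 0 or from 1 is not given in the sources used here, so positions are printed as deposited and may be off by 1 bp at the start. Tag counts, fold enrichments, false discovery rates and summits were not analysed here, and the depth of both libraries is unknown. No column held values of a single library, so the input could not be measured separately from the peaks.

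Scripts were written in Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9. Peak width was the end minus the start, and the interval of a median was the exact 95% binomial interval of its order statistics. The number of peaks on each chromosome was set against the chromosome's share of the summed reach, taken as the position of its last peak, by an exact two-sided binomial test with Benjamini-Hochberg adjustment over 20 chromosomes. The plan fixed before the data were examined called for chromosome lengths. No mm9 sequence was used here, so the last called position replaced them. Spacing was measured as the share of peaks whose midpoint had another midpoint within 100 kb. It was compared with 10000 random placements of the same widths without overlap between the first and last peak of the same chromosome. Two-sided p-values from these placements cannot go below 0.0002. The relation of width to score was tested with 100000 permutations. All of these tests treat peaks of 1 list as units. Peaks are not replicates, so the p-values describe the arrangement of this list and not the variation between embryos or experiments.

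The rule for items to name, fixed before the data were examined, took the 10 peaks with the highest score. Its other parts, which named genes and members of 14 fixed gene lists, rested on an annotation of mm9 or on gene names in the file. Assignment of peaks to genes, the gene lists, promoter, exon and intron shares, distances to transcription start sites and base composition were not analysed here, because the gene table at hand was built on GRCm38 and coordinates were not converted between builds. The windows of 1 Mb with 8 or more peaks were named after the positions had been seen.

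The tests were tested on simulated lists of 1341 peaks. The spacing test called 40 of 40 lists in which peaks had been placed next to others, and 4 of 40 random lists, each judged with fewer placements than the real list. With chromosome X simulated at 20% of its share, X was called low in 40 of 40 lists, and other chromosomes, simulated in proportion to their reach, were called 6 times over these 40 lists. With an even density X was called low in 0 of 40 lists, and other chromosomes were called 2 times over all 40. Peaks in these lists were assigned to chromosomes independently, so the effect of close spacing on the chromosome test was not checked. The correlation test called 40 of 40 lists simulated at r of 0.5 and 0 of 40 at r of 0. Alternatives were a minimum score of 100, merging of peaks within 1 kb, removal of the widest 5% of peaks, autosomes only, and windows of 10 kb and 1 Mb. Added after the data had been seen were the length from first to last call, random shifts within 1 Mb, removal of the windows with 8 or more peaks, and the weaker peaks alone for the relation of width to strength.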

Results

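Satb2 is a DNA-binding protein that attaches to matrix attachment regions and takes part in specifying projection neurons of the cerebral cortex that send axons through the corpus callosum. Its binding sites were mapped in mouse cortex at embryonic day 15 by ChIP-seq, with 1 Satb2 library and 1 input library. The deposited result was a single list of 1341 peaks. Because there was 1 library of each kind, no value below has a replicate error, and the strength of a peak is the score that the authors' peak caller gave to it, 10 times the −log10 of its p-value. Read depth is unknown for both libraries.

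The 1341 peaks covered 1.69 Mb of the mm9 genome and lay on all 19 autosomes and on chromosome X. The median width was 1201 bp, with an exact 95% interval of 1187 to 1218 bp. Widths ran from 600 to 3719 bp, and the middle 50% lay between 1050 and 1389 bp. The median score was 77.2, with an exact 95% interval of 74.9 to 79.0. The distribution had a long upper tail that reached 3179. A score of at least 100 was found in 420 peaks (31.3%), of at least 200 in 111 peaks (8.28%), of at least 500 in 26 peaks (1.94%) and of at least 1000 in 13 peaks (0.969%). The 10 strongest peaks held 11.8% of the summed score of the list.

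The 10 strongest peaks lay on 8 chromosomes, 3 of them on chromosome 7. The strongest was at chromosome 11, 104410771 to 104412586, with a score of 3179. The next was at chromosome 7, 148513124 to 148514696, with 2722. A peak at chromosome 14, 55304549 to 55306481, had 2340, and one at chromosome 4, 154597174 to 154598405, had 2231. The second peak of chromosome 7 among the strongest, 16984471 to 16986273, had a value of 1962. The sixth was at chromosome 1, 63222789 to 63224155, with 1532, and the seventh at chromosome X, 96131723 to 96133646, with 1349. A peak at chromosome 8, 73300064 to 73301960, had 1241, and one at chromosome 19, 9015693 to 9017339, had 1151. The tenth, at chromosome 7, 5012280 to 5014046, had 1100, close to the 1092 of the peak that followed it. None of these 10 peaks had another peak within 100 kb, and the distance to the nearest one ran from 269 kb to 4414 kb. Their widths were 1231 to 1932 bp, with a median of 1784 bp, and none of them was among the 10 widest. The widest peaks were at chromosome 16, 77236052 to 77239771 (3719 bp, score of 271), and chromosome 12, 51220521 to 51224225 (3704 bp, 659).

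Stronger peaks were wider across the list. The median width rose from 1052 bp in the 269 weakest peaks to 1502.5 bp in the 268 strongest. Across the 1341 peaks, Spearman's rho between width and score was 0.58 and Pearson's r was 0.30. Both had a permutation p of 1e-05, the smallest that 100000 permutations can give. Width and score both come from the peak caller and the same reads, so the relation describes the caller's measures and not Satb2 binding. The plan also named fold enrichment and tag count, which were not analysed here. Width against score was the only relation run, so no adjustment was made. Pearson's r fell to 0.16 (permutation p = 0.00353) and rho to 0.33 among the 420 peaks of at least 100. Among the 921 peaks below 100, r was 0.33 and rho 0.36. Each subset spans a narrower range of scores, which can by itself lower a correlation. The fall therefore does not show that the relation is weaker among strong peaks.

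**Figure D1:**
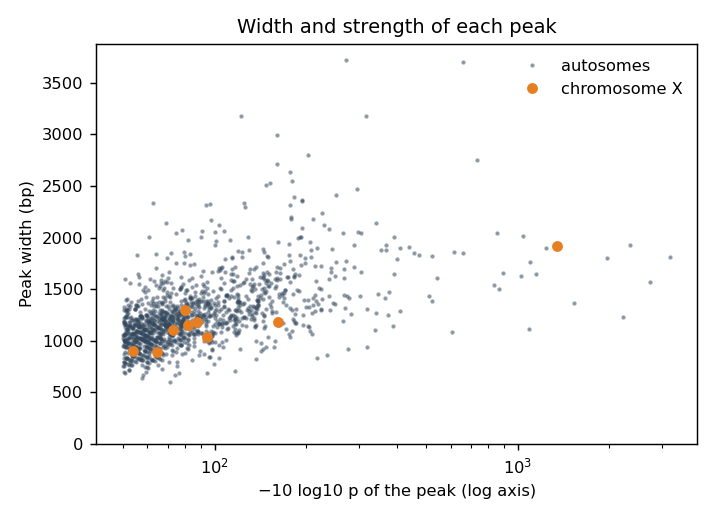
Each point is 1 peak, with its score on a log axis and its width in bp on the vertical axis, and the 9 peaks of chromosome X are marked. Width increased with strength (Spearman's rho 0.58). The 10 strongest peaks had widths of 1231 to 1932 bp. Their median of 1784 bp lay above the list's median of 1201 bp, and all were narrower than the widest peak at 3719 bp.

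Chromosome X carried few peaks. It held 9 of 1341 peaks, 0.671% of the list, where its reach of 163 Mb gave an expectation of 84.6. The ratio of observed to expected was 0.106, with an exact 95% interval of 0.0487 to 0.201 that covers counting error only (exact two-sided binomial test, adjusted p = 5.58e-25 over 20 chromosomes). In density, X had 0.0553 peaks per Mb and the autosomes together had 0.551 per Mb. The median score of the 9 peaks was 81.7, inside the range of autosomal medians from 70.9 to 83.1. Because the list holds only scores of at least 50, this median cannot show whether scores on X were lowered.

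Chromosome 18 was denser than its size gave. It held 75 peaks against 46.3 expected, a ratio of 1.62 with a 95% interval of 1.28 to 2.02 (exact binomial test, adjusted p = 0.00067). Chromosome 2 held 120 peaks against 90.4 expected, a ratio of 1.33 with an interval of 1.11 to 1.57 (exact binomial test, adjusted p = 0.012). These intervals cover counting error only, and the test takes peaks as independent. Because peaks lay close together, as given below, the intervals are too narrow and the p-values too small. The call for chromosome 2 did not hold among the 420 peaks of at least 100 (ratio 1.31, exact binomial test, adjusted p = 0.498) or without X in the expectation. With autosomes only, its ratio was 1.25 and its adjusted p 0.12 in the exact binomial test, while chromosome 18 stayed past the threshold with a ratio of 1.53 and an adjusted p of 0.00855. The other 17 chromosomes did not pass the adjusted test, chromosome 13 with 80 peaks and a ratio of 1.32 being the nearest (exact binomial test, adjusted p = 0.0734). Ratios among the autosomes ran from 0.738 on chromosome 17 to 1.62 on chromosome 18. The ranks of the scores, which weigh typical rather than extreme peaks, showed no detectable difference between chromosomes (permutation test of the Kruskal-Wallis statistic, 10000 permutations, p = 0.76). Of the 26 peaks of at least 500, 6 lay on chromosome 7, which held 71 of all 1341 peaks. This count was picked out after the data had been seen. Its test, given below, did not pass once adjusted over the 4 hypotheses chosen in that way.

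**Figure D2:**
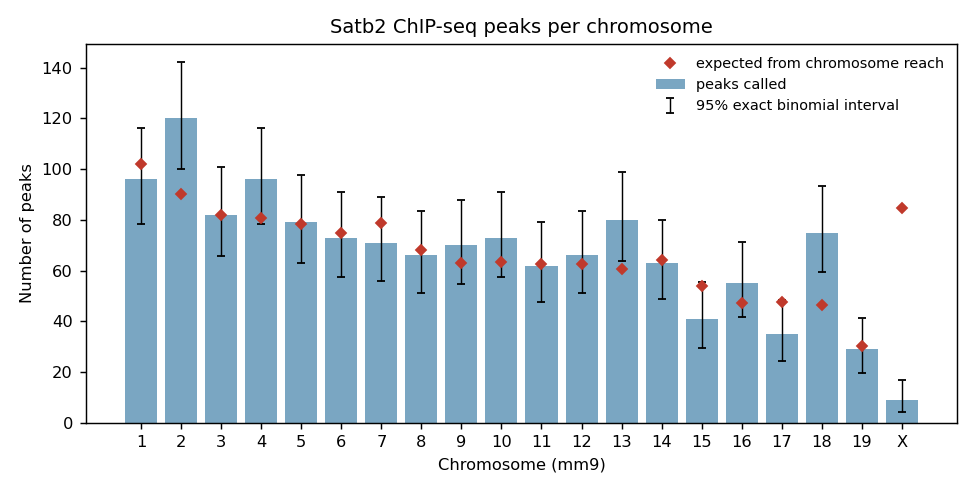
Bars give the number of Satb2 peaks on each mm9 chromosome with exact 95% binomial intervals, and diamonds give the number expected from the chromosome's reach. Chromosome X, with 9 peaks, lies far below its expectation of 84.6, and chromosomes 18 and 2 lie above theirs.

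Peaks lay closer together than random placement gave. Of the 1341 peaks, 355 (26.5%) had another peak within 100 kb. Random placements on the same chromosomes gave 10.9% ± 1.16 (SD over 10000 placements), and the highest of them was 16.3% (two-sided permutation p = 0.0002, the smallest these placements can give). Within 10 kb the share was 5.74% against 1.02% at random, and within 1 Mb it was 74.4% against 68.2%, each with the same permutation p of 0.0002. The median gap between neighbouring peaks was 911 kb, and gaps ran from 75 bp to 36.1 Mb. Of 1321 neighbouring pairs, 11 were separated by less than 1 kb and 203 by less than 100 kb. Merging the peaks within 1 kb left 1330 peaks, of which 25.5% had another within 100 kb.

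**Figure D3:**
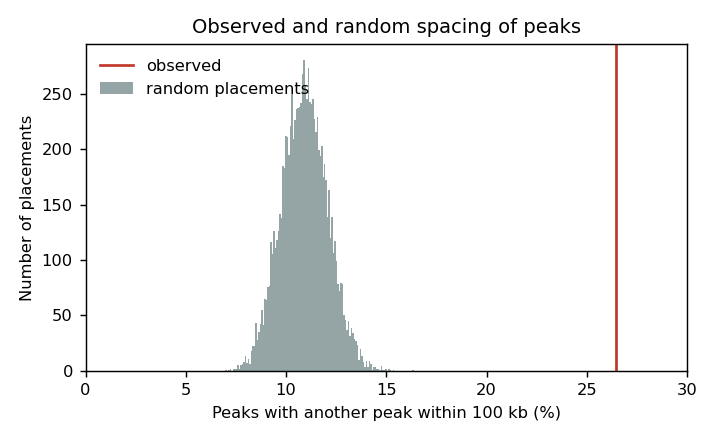
The histogram gives, for 10000 random placements, the percentage of peaks with another peak within 100 kb, and the line marks the deposited list. The observed 26.5% lies above the highest random value of 16.3%.

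Several regions held many peaks each. The densest 1 Mb window lay on chromosome 13, where 13 peaks fell between 84011964 and 84923982, 16.2% of the 80 peaks of that chromosome. Their median score was 151, and the strongest reached 391. On chromosome 18, 10 peaks lay between 54878847 and 55709990, with a median of 109 and a maximum of 250. Without these 10 peaks and with X kept in the expectation, chromosome 18 had a ratio of 1.41 and an adjusted p of 0.0446 in the exact binomial test. That value lay close to the threshold of 0.05. Leaving out both X and these peaks was not run, so whether the call would hold then is unknown. On chromosome 16, 9 peaks lay between 77099505 and 77853544, with a median of 137, and they included the widest peak of the list. A window on chromosome 2, 105355824 to 106295940, held 8 peaks with a median of 82.6. These 4 windows were the only separate ones with 8 or more peaks, and 5 further windows held 7 peaks each. In the random placements the densest 1 Mb window held 5.40 ± 0.648 peaks (mean ± SD over 10000 placements) and at most 10, and it held 8 or more in 49 of them. The windows were chosen because they were dense, so the strengths of their peaks are descriptive.

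**Figure D4:**
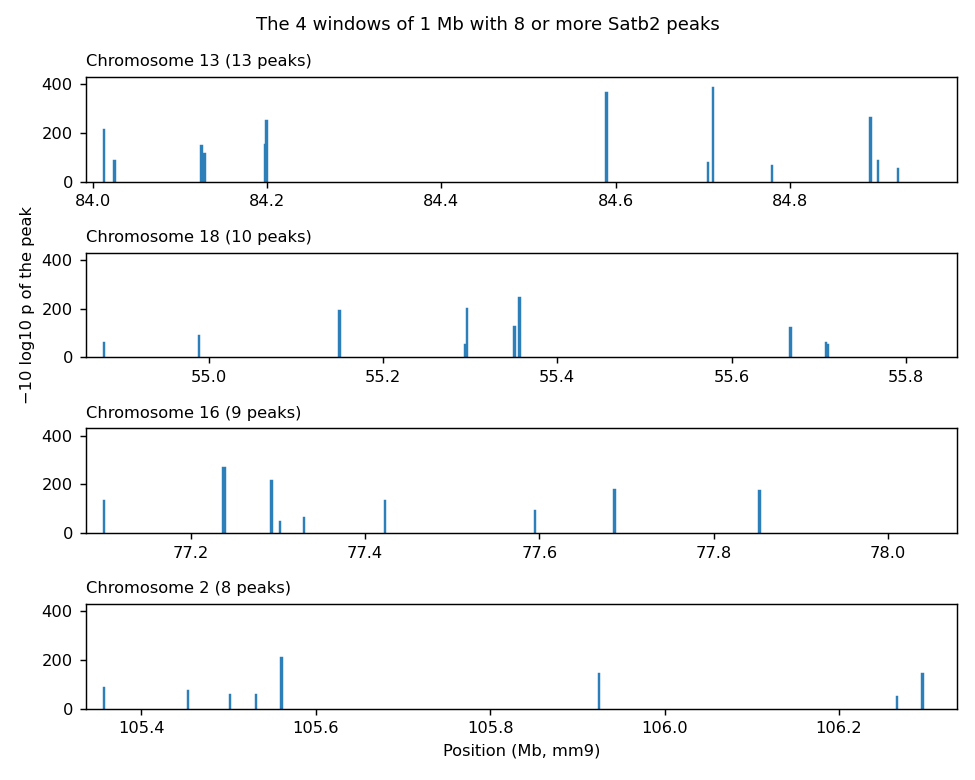
Each panel spans 1 Mb of mm9 and shows the peaks of 1 of the 4 windows with 8 or more peaks, drawn to scale in position, with the score of each peak as the height. The windows hold 13, 10, 9 and 8 peaks on chromosomes 13, 18, 16 and 2, and their strongest peak is the one of 391 on chromosome 13.

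At the scale of 10 Mb, the 271 bins from the chromosome starts to the last peaks held between 0 and 18 peaks. The highest count, 18, was found in 2 bins, at 70 to 80 Mb of chromosome 16 and at 50 to 60 Mb of chromosome 18. The next were 17 peaks at 80 to 90 Mb of chromosome 13 and 15 peaks at 100 to 110 Mb of chromosome 2. Empty bins numbered 14, and 9 of them were among the 17 bins of chromosome X.

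**Figure D5:**
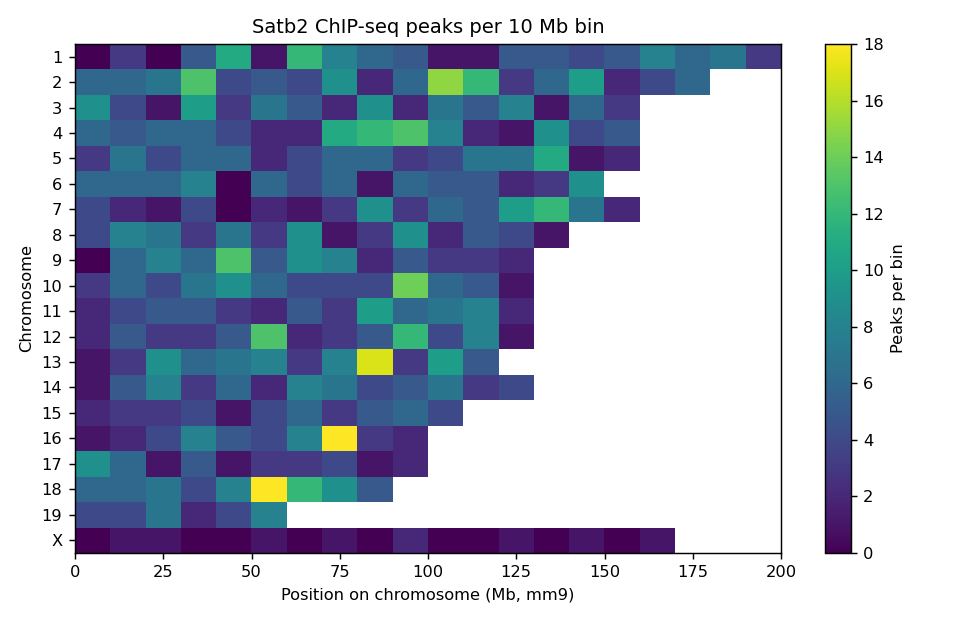
Colour gives the number of Satb2 peaks in each 10 Mb bin, with chromosomes as rows and the mm9 position in Mb along the horizontal axis, up to the last peak. The highest bins, with 18 peaks, lie on chromosomes 16 and 18, and 9 of the 17 bins of chromosome X are empty.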

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

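Of 36 alternatives that could change a value, 31 kept their direction and their side of the threshold, or for a count stayed within 1.5 times its value and for a width within its 95% interval. A fall from 3 chromosomes past the test to 2, among peaks of at least 100, is within that tolerance. None reversed a direction. The alternatives overlap, because a change to the chromosome test was counted for the number of chromosomes past it and again for chromosomes X, 2 and 18. Some could hardly move a value, such as removing peaks of chromosome 18 for the ratio of X. The total is therefore not a count of separate checks. Requiring a score of at least 100 left 420 peaks and raised the median width to 1432 bp, because it keeps the stronger and wider peaks. It also ended the call for chromosome 2 (ratio 1.31, exact binomial adjusted p = 0.498), with fewer peaks tested. With autosomes only, 1 chromosome passed the test in place of 3, because X was no longer tested and chromosome 2 no longer passed (ratio 1.25). The ratio for chromosome X stayed between 0.0755 and 0.114 over its alternatives, and that for chromosome 18 between 1.41 and 2.14. No alternative left out both X and the dense window of chromosome 18. The share of peaks with another within 100 kb stayed above its random range with merged peaks (25.5%), without the widest 5% (25.2%), without the 4 windows of 8 or more peaks (24.8%) and among peaks of at least 100 (13.3% against 3.77% at random). Shifting each peak at random by up to 1 Mb gave 16.8% against the observed 26.5%. Spearman's rho between width and strength was 0.36 below a score of 100 and 0.33 at or above it. Both were lower than the 0.58 over the whole list, but each subset spans a narrower range of scores. Alternatives on false discovery rate, fold enrichment, tag count and summit, and all those on gene lists, genomic features and sequence, were not run. No paired analysis was possible because each group had 1 library. For the same reason no library could be left out in turn. Without read depths, it is unknown how many sites fell short of the list's smallest score of 50.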

Other observations

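The tests of pair distances, of the densest window, of the strongest peaks, of position along the chromosome, of chromosome 7 and of the strength of close peaks were chosen after the result had been seen. Chromosome 7 held many of the strongest peaks. Of the 26 peaks with a score of at least 500, 6 lay on chromosome 7, which held 71 of all 1341 peaks, so that 8.45% of its peaks were this strong against 1.94% in the whole list (exact two-sided Fisher test, adjusted p = 0.035 over 20 chromosomes, and 0.14 once adjusted further over the 4 hypotheses of this kind). The threshold mattered. Before any adjustment, the exact Fisher p at 500 was 0.00176. Of 13 peaks of at least 1000, 3 lay on chromosome 7 (exact Fisher test, unadjusted p = 0.0277). Of 111 peaks of at least 200, 9 did (unadjusted p = 0.18 in the same exact test). The 6 peaks included the peaks at 148513124, 16984471 and 5012280 described above, and others starting at 13622751 (score of 891), 3644042 (851) and 123008778 (618). Those starting at 3644042, 5012280, 13622751 and 16984471 lay in the first 20 Mb of the chromosome, where the 10 Mb bins held 4 and 2 peaks. The high count thus came largely from that stretch, and the test, which takes peaks as independent, does not make it a trait of the whole chromosome.

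The low count on chromosome X was set against a technical explanation, a lower read depth on X, which cells with 1 X chromosome would give. A depth of 50% of the autosomes is the extreme of this explanation, with every cell carrying 1 X chromosome. A mixture with cells of 2 X chromosomes would lie above it. If a depth of 50% brought every score to 50% of its value, X would still hold calls at the autosomal rate of peaks of at least 100, which was 0.173 per Mb. The X rate was 0.320 times that rate (95% interval 0.145 to 0.613), so the deficit was larger than this scaling allows. The comparison at 100 was the one written before the test, and the comparison at 200 that follows was not part of it. The scaling is an assumption, however. A caller whose background has a genome-wide floor would lower the scores on X by more than the loss of depth, and the X rate was 1.22 times the autosomal rate of peaks of at least 200 (0.541 to 2.39), so that a fall of scores to 25% would be enough. The depth explanation therefore stays open, as do repeats on X that reads cannot be placed in, and no biological explanation was tested because the design gives no group that bears on it.

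The close spacing of peaks was set against 2 technical explanations. Splitting of 1 enriched region into several calls up to 10 kb apart would add only pairs at those distances. Pairs of neighbouring peaks with midpoints 10 to 100 kb apart numbered 161, against 68.6 ± 7.80 at random and at most 100 in 10000 placements, so such splitting does not account for the whole excess, and wider splits were not tested. Redrawing each peak inside its own 1 Mb bin, which keeps the count of every bin, gave a mean share of 19.3% with another peak within 100 kb and a 95% range of 17.0% to 21.6%, against 26.5% observed and 10.9% with full random placement. Uneven density between 1 Mb bins thus did not account for all of the excess. Whether it accounts for part cannot be told, because close spacing itself raises the bin counts that were kept. Unevenness over shorter stretches, from mappable sequence or from regions with several Satb2 sites, was not separated, and no biological explanation was tested.

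The densest window, with its 13 peaks on chromosome 13, exceeded the highest count of any random placement, which was 10, in 10000 placements. A further wide peak (3177 bp, score of 122) lay just before this window, from 83878810 to 83881987. Random placement ignores unmappable sequence and takes each call as a separate site. Some of the 13 calls lay within 10 kb of another, such as those starting at 84196164 and 84198371, and were not merged for this count. Even placement had also failed for the spacing of the whole list. The comparison therefore shows only that evenly placed separate calls did not give such a window, and it does not exclude chance.

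Apart from the tests of spacing and of the densest window, 4 hypotheses were tested after the data had been seen. The test of chromosome 7 passed over the chromosomes but not over the 4 hypotheses, and the other 3 did not pass. The 26 peaks of at least 500 had a median distance of 678 kb to their nearest peak, against 341 kb for the rest, but random draws of as many peaks gave 148 to 744 kb (two-sided permutation p = 0.10, adjusted p = 0.20 over the 4 hypotheses). Of these 26, 3 (11.5%) had another peak within 100 kb, against 26.8% of the rest. The direction depended on the threshold. At 1000 it was the same as at 500. The 13 peaks of at least 1000 had a median distance of 775 kb against 341 kb for the rest (two-sided permutation p = 0.14). Among them, 0% had another peak within 100 kb, against 26.7% of the rest. The 111 peaks of at least 200 had a median distance of 336 kb against 346 kb for the rest (two-sided permutation p = 0.83), and 28.8% of them had another within 100 kb, against 26.3%. From the 269 weakest to the 268 strongest peaks, the median distance went from 487 to 268 kb and the share within 100 kb from 21.9% to 29.5%, a trend that was not tested. Peaks with another within 100 kb had a median score of 78.5 and the others 76.7, a difference of 1.89 that lay inside the random range of −4.995 to 4.28 (two-sided permutation p = 0.40). The mean relative position between the first and last peak of a chromosome was 0.516 ± 0.0611 (SD over 20 chromosomes), above 0.5 in 12 of 20 (exact two-sided sign-flip p = 0.26).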
